A study of Mus musculus with 30 samples.

How the data were processed

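The samples were cultures of naive CD8-positive T cells of mice, taken from spleen and lymph nodes of C57BL/6 mice aged 8 weeks. Per the labels, the cells were kept for 3 days in serum-free medium on plates coated with antibodies against CD3 and CD28 (5 µg/ml each). The medium held no added cytokine, TGFB1 at 0.5 ng/ml or IL12 at 10 ng/ml. The animals were wild type (WT) or carried the Furin knockout (KO). KO stands throughout for the libraries labelled KO. Each of the 6 groups had 5 libraries, and each genotype had 4 females and 1 male.

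The deposited table held raw read counts per Ensembl gene, and its values were whole numbers. Per the submitters' processing notes, FastQC, Trim Galore, STAR and DESeq2 1.24.0 were used with the GRCm38 genome build. The labels name poly(A) purification and a directional library kit. The tool that counted reads, its strand setting and the annotation release are not given in the sources used here. Gene symbols and coordinates were looked up by Ensembl identifier in the GENCODE vM21 annotation of GRCm38. Of the 55573 genes in the table, 55394 had a symbol there, and the other 179 held 0.011% of the counts.

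Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with a minimum count of 10, which left 11718 genes with 99.88% of the counts. Libraries were scaled by TMM factors, and 1 model with a mean per group was fitted to all 30 libraries by edgeR quasi-likelihood. Each contrast was tested two-sided, and p values were adjusted over all genes tested by the Benjamini-Hochberg method. A gene is called where its adjusted p is below 0.05. The contrasts were KO against WT in each of the 3 conditions, each cytokine against no cytokine in each genotype, and the differences between the genotypes in both cytokine responses. An additional fit used the counts summed over the 3 libraries of each animal number. CPM (counts-per-million) were computed from the deposited counts with the TMM factors. The log2 CPM for the principal components and for the check of the animal numbers used a prior count of 1. Fold changes are given as log2 values with their standard error (SE). The biological coefficient of variation was 14.3%. In the main fit the p values rest on a spread per gene pooled over all 6 groups, with no term for the animal. The 3 libraries of each animal number count as separate units there.

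Lists of genes were fixed by symbol, 34 in all, and 32 of them had at least 3 measured members and were tested as sets. The set test was camera, which compares a list with all other tested genes, with a preset correlation between genes of 0.01. Adjusted p values were also computed with a correlation estimated per list and with fry, which tests whether a list's genes move one way. Members were called over all genes tested and also with p values adjusted over the list alone. The lists of erythroid and platelet markers and of stromal and endothelial markers had 1 and 2 measured members and were not tested.

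The genes named in the text follow a fixed rule. It takes 30 key genes, and per comparison the 8 called genes with the largest rise and the 8 with the largest fall among those with a symbol and at least 4 CPM in the higher group. For the differences between responses it takes the 8 with the smallest p. For each list called it takes the leading members. Any gene named outside the rule is marked as chosen after its values were seen. The rule, the lists, the tests and most alternatives were set before the data were examined.

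Library totals ran from 7306151 to 15502443 counts, and 3 counts over a group of 5 correspond to 0.067 CPM in WT without cytokine and 0.0625 CPM in KO without cytokine. For a gene with no counts in a group, the fold change is given as a lower bound against 3 counts over the group. For a gene with 1 to 3 counts there, the ratio of summed counts is given with an exact 95% interval. These intervals and floors cover counting error only.

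The numbers in the titles were checked as animals. All 10 numbers carried 1 genotype and 1 sex across their 3 libraries. After removal of the group means, the correlation of libraries sharing a number had a median of 0.222 over 30 pairs, from -0.034 to 0.43, and 23 of them were highest with their own number. The numbers were therefore used as a block in alternative fits. WT library 75 with IL12 had negative values with both other libraries of its number, -0.034 without cytokine and -0.014 with TGFB1. For that library the check did not bear out the animal number. No pair of libraries within a group had counts close enough to be copies of 1 library.

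Alternatives were other size factors, no filter and a stricter filter, a fold change minimum, DESeq2 1.42.0, limma-voom, a block for the animal number, a term for sex, females alone, fits on the compared groups alone and leaving out each library. Removal of a gene length trend, thinning to the smallest total, leaving out 2 WT libraries and a term for animal numbers above 70 were added after the data were seen. The scripts were tested on simulated data in which 200 genes were changed by known folds. For KO against WT without cytokine the test recovered 56% of genes changed 1.5-fold and 84% of genes changed 2-fold, with 3.5% false calls. For KO against WT with TGFB1 it recovered 62% and 78%, and for KO against WT with IL12 60% and 86%. The simulated counts of this test held no animal effects, deviating libraries or gene length trend. These rates may therefore not hold for the real libraries. Some genes of the lists are not reported here.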

Results

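RNA was sequenced from 30 cultures of naive CD8-positive T cells of mice after 3 days of stimulation through CD3 and CD28. They formed 6 groups of 5: WT and KO cells with no added cytokine, with TGFB1 and with IL12. TGFB1 restrains effector functions of T cells, and IL12 drives them toward an interferon-producing cytotoxic state. Furin encodes a proprotein convertase, an enzyme that cleaves precursor proteins such as that of TGFB1 into their active forms. Total counts per library were 8362026 to 9875726 in WT and 7621632 to 11292997 in KO without cytokine. With TGFB1 they were 8553822 to 11435315 in WT and 7522984 to 10859883 in KO, and with IL12 they were 7306151 to 10406630 in WT and 8464699 to 15502443 in KO. The first 3 principal components held 34.6%, 16.7% and 13.8% of the variance.

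Furin (ENSMUSG00000030530, GRCm38 chromosome 7, 80388585 to 80405436) was read at similar levels in both genotypes without cytokine and with TGFB1. Without cytokine its level was 36.15, 34.85, 34.27, 28.83 and 38.48 CPM in the 5 WT libraries and 32.53, 32.56, 32.59, 31.53 and 33.86 CPM in the 5 KO libraries. With TGFB1 it was 73.92, 75.27, 79.89, 93.16 and 82.25 CPM in WT and 65.96, 72.27, 90.2, 79.3 and 81.85 CPM in KO. With IL12 it was 161.4, 182.5, 511.1, 532.8 and 485 CPM in WT and 161, 120, 131.9, 195.7 and 463.5 CPM in KO. By the edgeR test KO and WT did not differ in any condition, with log2 fold changes of -0.08 (adjusted p = 0.914), -0.05 (adjusted p = 0.901) and -0.81 ± 0.28 SE (adjusted p = 0.0799). With a term for animal numbers above 70, added after the data were seen, Furin was called lower in KO with IL12 (log2 fold change of Furin, KO vs WT, with IL12 -0.48, adjusted p = 0.042), as it was without WT library 62, WT 67 or KO 74 with IL12 (adjusted p = 0.0156, 0.0236 and 0.00925). TGFB1 raised Furin by 1.23 on the log2 scale in WT (adjusted p = 0.00233) and 1.26 in KO (adjusted p = 0.00293), and IL12 raised it by 3.44 ± 0.32 in WT (adjusted p = 2.81e-08) and 2.72 ± 0.31 in KO (adjusted p = 7.77e-07). Counts per gene include exons outside any deleted part, and the labels do not say which part of Furin was deleted, so these levels do not check the labels.

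**Figure D1:**
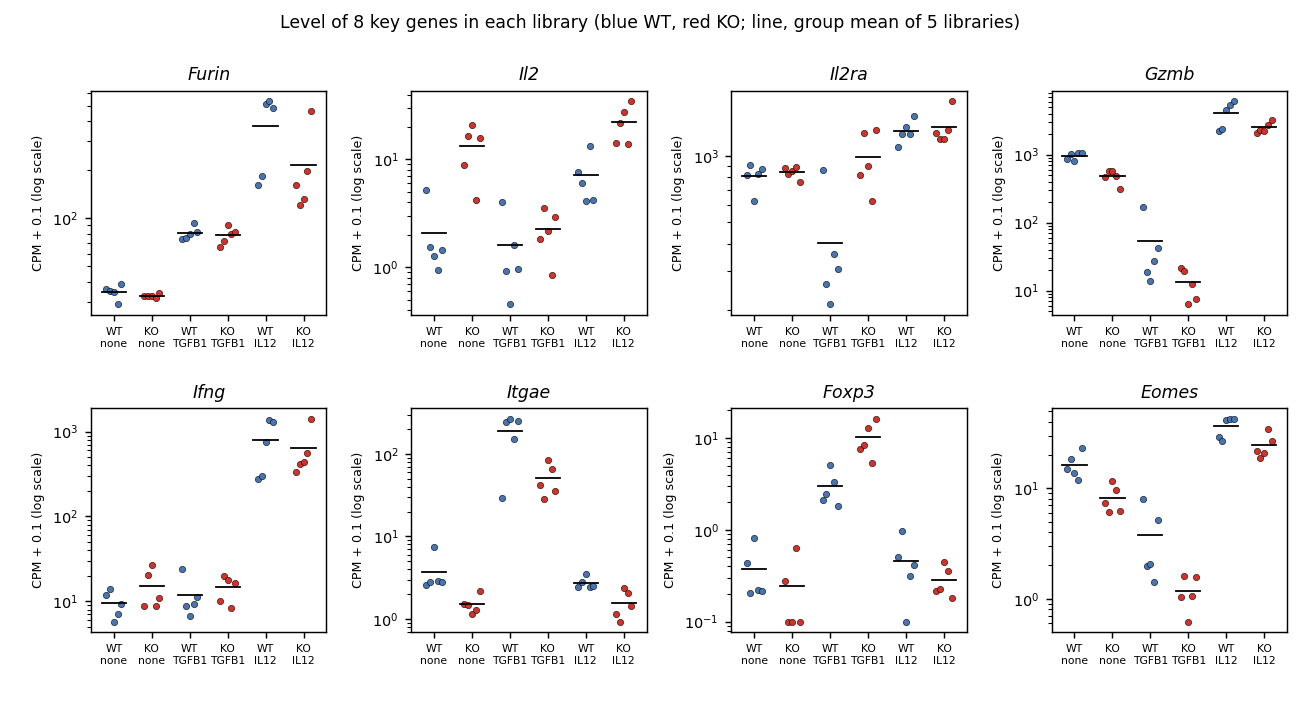
Level of 8 genes in each of the 30 libraries, as CPM plus 0.1 on a log axis, with the 6 groups along the horizontal axis, WT in blue and KO in red, and a line at the mean of 5. Furin averaged 375 CPM in WT and 214 CPM in KO with IL12, and the level of Itgae averaged 189 CPM in WT and 51.2 CPM in KO with TGFB1.

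Without added cytokine, the comparison of KO with WT asks how activated CD8 T cells labelled KO differed from those labelled WT. Il2, the main growth factor of T cells (ENSMUSG00000027720, chromosome 3, 37120523 to 37125959), averaged 13.3 ± 6.71 CPM (SD, n = 5) in KO and 1.99 ± 1.77 CPM (SD, n = 5) in WT, a log2 fold change of 2.71 ± 0.50 SE (adjusted p = 0.0105). Without WT library 62, which held 5.116 CPM, it was 3.43. Pdgfb, a growth factor whose precursor is processed by convertases (ENSMUSG00000000489, chromosome 15, 79995874 to 80014977), rose by 1.64 ± 0.27 (adjusted p = 0.00344). Rgs16, a brake on G-protein signalling, rose by 1.38 ± 0.27, and Spp1, the cytokine osteopontin, by 1.53 ± 0.32. Trim66, Kcnk10, Pls1 and Cnih3 completed the 8 largest rises among genes with at least 4 CPM in the higher group. Plaur, the urokinase receptor (ENSMUSG00000046223, chromosome 7, 24462484 to 24475968), fell by 2.28 ± 0.49. Cables1 fell by 1.60, Bmf, which promotes apoptosis, by 1.30 and Isg15, an interferon-induced ubiquitin-like protein, by 1.30. Gzmb, which encodes the killing protease granzyme B, averaged 484.9 ± 107 CPM in KO and 959.3 ± 119 CPM in WT and was not called (log2 fold change -0.98 ± 0.41, adjusted p = 0.195). Its levels did not overlap, with at most 583 CPM in KO and at least 804.6 CPM in WT. The SE comes from the spread pooled over all 6 groups, so the missing call does not show equal levels.

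Interferon-response genes were lower in KO without cytokine. Of 32 measured members of the interferon-gamma list, 6 fell and 0 rose, among them Irf1 (-0.53), Tap1 (-0.38), which loads peptides on MHC class I, and Irgm1 (-0.39), and 23 fell when adjusted over the list alone. The list's median log2 fold change was -0.40, with camera adjusted p = 1.49e-14 and adjusted p = 0.248 with an estimated correlation. Of 27 members of the type I interferon list, 6 fell, with Ifit3 at -2.10 and Stat2 at -0.93, and 15 fell when adjusted over the list alone. The median was -0.96. Camera gave adjusted p = 3.72e-13, and adjusted p = 0.248 with an estimated correlation. Genes of T-cell activation were higher: 6 of 27 rose, including the costimulatory receptors Icos (0.52) and Tnfrsf4 (0.68), and 9 when adjusted over the list alone. As a set the camera adjusted p was 2.4e-06, and adjusted p = 0.26 with an estimated correlation. Of 19 cytokines and chemokines, Il2, Ccl3 (1.21) and Ccl4 rose, and 9 rose and 1 fell when adjusted over the list alone. Tested as a list by camera, they had adjusted p = 0.000121, and adjusted p = 0.275 with an estimated correlation. Of 18 genes in the list of inhibitory receptors and exhaustion, Rgs16, which is not a receptor, and Btla (0.57) and Pdcd1 (0.78) rose, and 5 when adjusted over the list alone. The list test by camera gave adjusted p = 0.0021, and adjusted p = 0.0714 with an estimated correlation. Of 24 cytokine receptors, Ifngr2 (-1.20), Il7r (-1.26), Il2rb (-0.56) and Il4ra (-0.61) fell, and 9 fell and 1 rose when adjusted over the list alone. For this list the camera adjusted p was 0.00665, and adjusted p = 0.26 with an estimated correlation. The IL2/STAT5 response list was also called by camera. That call ended in 6 of the fits without 1 library (highest adjusted p = 0.116), by fry and with an estimated correlation. It also ended with the gene length trend removed (median -0.316, camera adjusted p = 0.0607). Of 13 measured FURIN substrates and TGFB activators, Pdgfb alone passed the test over all genes (camera adjusted p = 0.0864), and 2 rose and 1 fell when adjusted over the list alone. Genes of the G2 and M phases had a median of -0.14 there, with 0 of 30 called over all genes or adjusted over the list alone (camera adjusted p = 0.000608, adjusted p = 0.775 with an estimated correlation).

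The next numbers are of genes called: KO vs WT, no added cytokine. The comparison gave 246 of 11718 genes, 126 higher and 120 lower in KO, and 36 and 32 of these by at least 2-fold. This count rests on single libraries: it was 7 without KO library 74, 11 without KO 68, 14 without WT 72, 17 without WT 71, 28 without KO 70, 100 without WT 75 and 568 without KO 73. Il2 and Pdgfb stayed called whichever library was left out, while every other gene given above as higher or lower lost its call without at least 1 of these libraries, with adjusted p for example of 0.0811 for Plaur and 0.0752 for Spp1 without KO 74, 0.0547 for Rgs16 without WT 72 and 0.13 for Isg15 without KO 68. DESeq2 called 460 genes, and a fit on these 10 libraries alone called 1099.

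**Figure D2:**
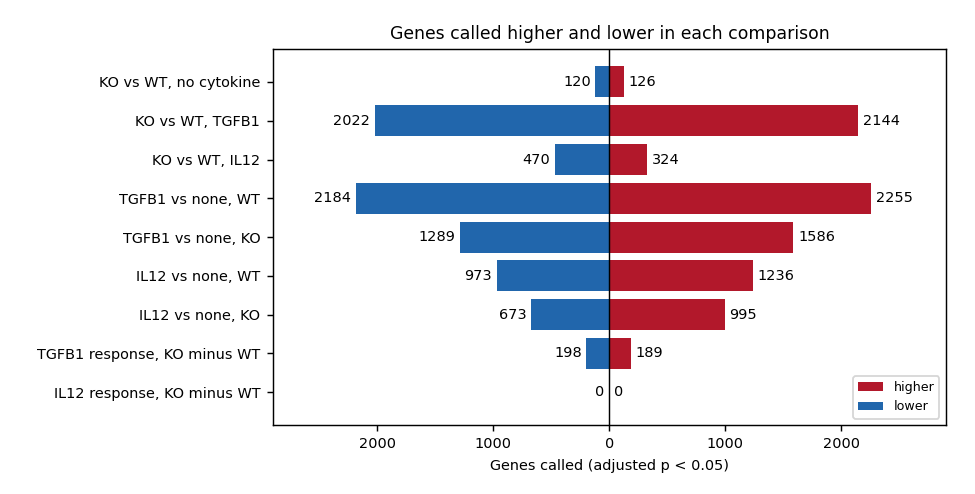
Number of genes called higher and lower by edgeR in each of 9 comparisons, as bars from 0. KO against WT gave 246 genes without cytokine, 4166 with TGFB1 and 794 with IL12.

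With TGFB1, the comparison of KO with WT asks how the cells labelled KO differed under this cytokine. Itgae, the integrin chain CD103 that binds epithelium (ENSMUSG00000005947, chromosome 11, 73090583 to 73147446), averaged 51.2 ± 23.4 CPM (SD, n = 5) in KO and 189 ± 101 CPM (SD, n = 5) in WT, a log2 fold change of -1.88 ± 0.34 SE (adjusted p = 0.000391). Gzmb (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260) averaged 13.3 ± 6.83 CPM in KO and 53.6 ± 64.2 CPM in WT (-2.02 ± 0.48, adjusted p = 0.00238). Without WT library 62, which held 166.8 CPM, the fold change was -0.95 on the log2 scale (adjusted p = 0.0254). Eomes, a T-box factor of effector and memory cells, fell by 1.72 ± 0.43 (adjusted p = 0.00336), and Stat4, which relays the IL12 signal, by 0.87 ± 0.16 (adjusted p = 0.000364). Foxp3, the factor of regulatory T cells (ENSMUSG00000039521, chromosome X, 7573644 to 7595245), was higher, at 10.1 ± 4.42 CPM in KO and 2.87 ± 1.33 CPM in WT (1.79 ± 0.37, adjusted p = 0.000898). Il2ra, a chain of the IL2 receptor (ENSMUSG00000026770, chromosome 2, 11642807 to 11693193), was also higher, at 987.7 ± 298.6 CPM in KO and 400.7 ± 266 CPM in WT (1.30 ± 0.25, adjusted p = 0.000474). The inhibitory SMAD gene Smad7 fell by 0.85 ± 0.23 (adjusted p = 0.00608) and the naive-cell gene Tcf7 by 1.01 ± 0.30. In a fit on the libraries with TGFB1 alone the adjusted p was 0.0506 for Gzmb, 0.0519 for Smad7 and 0.0549 for Tcf7, so these 3 calls ended.

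Interferon-induced genes fell in KO with TGFB1: Ifi206 fell by 4.24 ± 0.70, Irf7, which drives type I interferon transcription (ENSMUSG00000025498, chromosome 7, 141262706 to 141266481), by 3.24 ± 0.50, and Rtp4, Ifi214 and Xaf1 by 2.90, 2.43 and 2.38. Of 27 type I interferon genes 20 fell and 0 rose, both over all genes and adjusted over the list alone. Their median was -1.22. Camera gave adjusted p = 6.28e-12, and adjusted p = 0.448 with an estimated correlation. Of 32 interferon-gamma genes 14 fell and 1 rose, with the immunoproteasome genes Psmb8 (-0.76) and Psmb10 (-0.87) among the falls, and 18 fell and 1 rose when adjusted over the list alone. As a set the camera adjusted p was 4.32e-05, and adjusted p = 0.534 with an estimated correlation. Of 22 naive and memory genes 14 fell and 0 rose, the same numbers as when adjusted over the list alone, with Dapl1 at -1.51, Id3 at -1.66 and Cd27 at -0.92. Tested as a list by camera, they had adjusted p = 6.95e-06, and adjusted p = 0.479 with an estimated correlation. Of 14 cytotoxic effectors 9 fell and 2 rose, also when adjusted over the list alone, with the granzyme inhibitor Serpinb9 at -1.32 ± 0.30 (camera adjusted p = 0.016, adjusted p = 0.479 with an estimated correlation), and this list call ended without WT library 62 (adjusted p = 0.0641). Of 25 homing receptors and integrins 12 fell and 2 rose, and 13 and 3 when adjusted over the list alone, including Itga4 (-1.27) and Itgb7 (-1.48), chains of a gut-homing integrin. The list test by camera gave adjusted p = 0.0145, and adjusted p = 0.5 with an estimated correlation. Bcl6, a repressor of effector programmes, fell by 2.42 ± 0.39. Of 30 genes of the G2 and M phases 14 fell and 0 rose, such as the mitotic genes Birc5 (-0.50) and Ccnb2 (-0.72), and 15 fell when adjusted over the list alone. They had a median of -0.23 and camera adjusted p = 4.58e-05, and adjusted p = 0.525 with an estimated correlation.

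Genes of cholesterol synthesis and of the amino acid response were higher in KO with TGFB1. Of 26 genes of cholesterol synthesis 23 rose and 0 fell, also when adjusted over the list alone, including Sqle (0.75 ± 0.13; ENSMUSG00000022351, chromosome 15, 59315077 to 59331192), Sc5d (0.81) and Nsdhl (0.64), enzymes of the sterol pathway. Their median was 0.64. For this list the camera adjusted p was 2.01e-13, and adjusted p = 0.448 with an estimated correlation. Of 25 genes of the amino acid response driven by ATF4 18 rose and 2 fell, with the serine enzyme Psat1 at 0.75 ± 0.13 and the asparagine synthetase Asns at 0.95 ± 0.19, and 21 rose and 3 fell when adjusted over the list alone. Camera gave adjusted p = 1.67e-07, and adjusted p = 0.479 with an estimated correlation. Of 27 genes of T-cell activation 11 rose and 1 fell, also when adjusted over the list alone, among them the transferrin receptor Tfrc (1.06 ± 0.17) (camera adjusted p = 0.0281, adjusted p = 0.664 with an estimated correlation). This list call ended in 3 of the fits without 1 library, with the highest adjusted p, 0.082, without WT library 71. Of 20 genes of the TGFB/SMAD response 3 rose and 4 fell, both over all genes and adjusted over the list alone, and the list was not called (camera adjusted p = 0.629). Oxidative phosphorylation (3 of 32 rose and 3 fell, camera adjusted p = 0.736) and glycolysis (9 of 28 rose and 2 fell, camera adjusted p = 0.061) were not called, and 1 and 1, and 11 and 3, did so when adjusted over the list alone. The other large rises included Nat8l (2.74 ± 0.44), Cyp1b1 (2.62 ± 0.43), an enzyme induced through the aryl hydrocarbon receptor, Dock4 (2.32 ± 0.32) and the cytokine Il1a (2.18 ± 0.57).

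The numbers here are of genes called: KO vs WT, with TGFB1. The comparison gave 4166 genes, 35.6% of those tested, 2144 higher and 2022 lower in KO, with 174 and 347 of them by at least 2-fold. Leaving out single libraries gave 2814 to 5367 genes, and the fit on these 10 libraries alone gave 2271. Gzma (-3.085 ± 0.97) lost its call without WT library 75 (adjusted p = 0.0148 with all libraries and 0.0708 without).

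With IL12, the comparison of KO with WT asks the same under a cytokine that drives effector cells. Il2 was higher again in KO, at 22.3 ± 8.78 CPM (SD, n = 5) against 7.02 ± 3.83 CPM (SD, n = 5) in WT. Pls1, which bundles actin filaments (ENSMUSG00000049493, chromosome 9, 95752642 to 95845311), rose by 1.96 ± 0.27 SE (adjusted p = 0.000169), the 1 gene of those named here that stayed called in every alternative. Inhba, a chain of activin, rose by 2.95 ± 0.54 (adjusted p = 0.00327; log2 fold change 1.97 without KO library 74), and Gucy1a1, a chain of the nitric oxide receptor, by 1.55 ± 0.27 (adjusted p = 0.00234). Plaur fell by 2.20 ± 0.43 (adjusted p = 0.00459) and Tmprss6, a membrane serine protease, by 2.22 ± 0.43 (adjusted p = 0.00436). The cytokine gene Il10 averaged 1.08 ± 0.81 CPM in KO and 6.06 ± 5.36 CPM in WT (adjusted p = 0.0132), and Gzma, another granzyme, 2.19 ± 1.17 and 11.9 ± 11.2 CPM (adjusted p = 0.0141). Ifng (796.1 ± 520 CPM in WT and 637.6 ± 448 CPM in KO) and Gzmb (4149 ± 1745 and 2515 ± 475 CPM) were not called.

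Interferon-gamma response genes were lower in KO with IL12 as well: 9 of 32 fell, including Irf1 (-0.70 ± 0.13) and the immunoproteasome genes Psmb9 (-0.42) and Psmb10 (-0.55), and 18 fell when adjusted over the list alone. Their median was -0.43. As a set the camera adjusted p was 7.9e-12, and adjusted p = 0.762 with an estimated correlation. Of 27 type I interferon genes 5 fell, such as Oasl2 (-2.54) and Zbp1 (-0.84), and 8 when adjusted over the list alone. Tested as a list by camera, they had adjusted p = 4.42e-06, and adjusted p = 0.857 with an estimated correlation. Of 32 genes of oxidative phosphorylation 8 fell, among them the respiratory chain genes Cox5b (-0.42 ± 0.08) and Cox4i1 (-0.40 ± 0.09), and 13 when adjusted over the list alone. Their median was -0.14. The list test by camera gave adjusted p = 1.07e-07, and adjusted p = 0.762 with an estimated correlation. Without WT libraries 72 and 75 the median was -0.035, 0 members were called and the list call ended (adjusted p = 0.147), and with the gene length trend removed the median was -0.072 (adjusted p = 0.000103). The fold changes of this comparison followed gene length across genes, which are not independent replicates (Spearman rho 0.281). Ribosomal protein genes took 7.24 ± 0.33% of the counts in KO and 8.68 ± 1.21% in WT (SD, n = 5), and mitochondrial transcripts 1.51 ± 0.51% and 1.19 ± 0.34%. The ribosomal share was 9.745% and 10.178% in WT 72 and 75, 7.457%, 7.82% and 8.207% in the other WT libraries and 6.685% to 7.568% in KO. Levels relative to the mean of all libraries followed gene length with Spearman rho -0.296 and -0.343 in WT 72 and 75. In the other libraries with IL12 this rho was -0.015 to 0.203. Of 25 genes of the IL12/STAT4 response 4 fell and 1 rose, and 9 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.0114, adjusted p = 0.857 with an estimated correlation), and that list call ended without WT library 71 (adjusted p = 0.0995), without any 1 of 4 other libraries (WT 72, WT 75, KO 63 and KO 68), by fry, without WT 72 and 75 together and with a term for animal numbers above 70. Of 13 FURIN substrates and TGFB activators Pdgfb rose (1.48 ± 0.25), and 3 when adjusted over the list alone. Camera gave them adjusted p = 0.0444, and adjusted p = 0.762 with an estimated correlation. That call ended without any 1 of 5 libraries (highest adjusted p = 0.13, without WT 75; also WT 72, KO 63, KO 70 and KO 73), without WT 72 and 75, with that term and with the gene length trend removed (adjusted p = 0.134). Of the G2 and M genes Dlgap5 (-0.36) fell, also when adjusted over the list alone (median -0.14, camera adjusted p = 0.00276, adjusted p = 0.857 with an estimated correlation), and the call of Dlgap5 ended without WT library 75, without WT 72 and 75 and when only the libraries of the 2 groups were fitted.

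These are the numbers of genes called: KO vs WT, with IL12. The comparison gave 794 genes, 324 higher and 470 lower in KO, and 49 and 55 by at least 2-fold. The number was 164 without WT library 75, 231 without WT 72, 272 without KO 68, 360 without KO 70, 522 without WT 71, 1231 without WT 67 and 1532 without WT 62. It was 35 in a fit on these 10 libraries and 8 without WT libraries 72 and 75 together. Without WT 75 the adjusted p was 0.076 for Il2, 0.0577 for Il10, 0.0848 for Gzma, 0.131 for Oasl2, 0.0509 for Psmb9 and 0.0642 for Cox4i1, and without KO 68 it was 0.0807 for Zbp1. Without WT 72 and 75 the calls of Plaur, Tmprss6, Gucy1a1, Irf1 and Psmb10 also ended (adjusted p = 0.0848, 0.0897, 0.0823, 0.0823 and 0.208), as did that of Cox5b (adjusted p = 0.178). The call of Inhba ended in the fit on 10 libraries (adjusted p = 0.0716).

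Across the 3 conditions, 55 genes were called for KO against WT in each, 21 higher and 34 lower, and 0 changed direction. At most 7 of them can stay without KO library 74 without cytokine, and at most 8 without WT libraries 72 and 75 with IL12, as no more genes were called then. Those named next were chosen after their values were seen. Higher in KO were Twist1, a factor that limits inflammatory T cells (log2 fold changes of 2.64, 1.74 and 1.93 without cytokine, with TGFB1 and with IL12), Pdgfb (1.64, 0.63 and 1.48) and the carboxypeptidase gene Cpd (1.20, 0.76 and 1.46), which trims basic residues after convertase cleavage. Lower in KO were the tetraspanin gene Tspan9 (-2.36, -2.97 and -2.98), Ifit3 (-2.10, -2.97 and -1.97), Irf1 (-0.53, -0.55 and -0.70) and Il2rb (-0.56, -0.69 and -0.46), a chain of the IL2 and IL15 receptors. Of the 126 genes higher in KO without cytokine 61 were also higher with IL12 and 42 with TGFB1, and of the 120 lower genes 48 and 69 were also lower. Independent lists would share 3.5 and 23.1 of the higher genes and 4.8 and 20.7 of the lower genes. These comparisons share animals but no libraries, so they are not independent. Counts summed over the libraries of each animal gave the genes called: KO vs WT, 3 libraries summed per animal number. The comparison gave 2400 of 12709 genes, 1167 higher and 1233 lower in KO, with Irf7 lower by 2.42 ± 0.40 (adjusted p = 0.0132) and Twist1 higher by 2.12 ± 0.41 (adjusted p = 0.0154; 0.0508 without KO animal 68). That number was 148 without KO animal 68, 372 without KO 70, 472 without WT 75, 541 without KO 74, 549 without WT 71, 1220 without WT 72 and 3741 without WT 62.

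**Figure D3:**
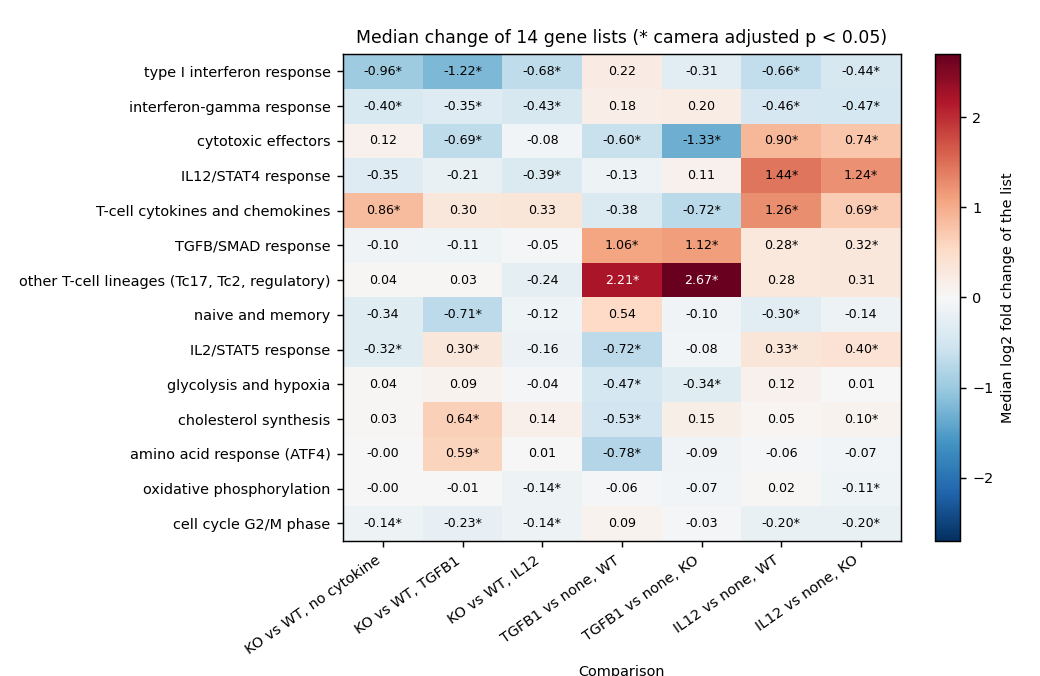
Median log2 fold change of 14 gene lists (vertical axis) in 7 comparisons (horizontal axis), as a colour scale, with a star where the camera adjusted p is below 0.05. The TGFB/SMAD response is starred in both comparisons of TGFB1 with no cytokine and also in both comparisons of IL12 with no cytokine. The IL12/STAT4 response is starred in both comparisons of IL12 with no cytokine and in KO against WT with IL12.

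TGFB1 against no cytokine asks what the cytokine did in each genotype. In both, most measured genes of the TGFB/SMAD response and of other T-cell lineages rose, and cytotoxic effectors fell on balance. Nt5e, the ectoenzyme CD73 (ENSMUSG00000032420, chromosome 9, 88327197 to 88372092), rose by 5.45 ± 0.33 SE on the log2 scale in WT (n = 5 per group; adjusted p = 6.71e-13) and 5.38 ± 0.32 in KO (adjusted p = 9.08e-13). Itgae rose by 5.73 ± 0.45 in WT and 5.14 ± 0.49 in KO. Maf (ENSMUSG00000055435, chromosome 8, 115682942 to 115707794) and the cytokine gene Il17f, both features of Th17-type cells, rose by 7.72 ± 0.73 and 6.13 ± 0.63 in WT and by 7.59 ± 0.71 and 6.40 ± 0.62 in KO. Gzmb fell by 4.17 ± 0.47 in WT (log2 fold change -5.24 without WT library 62 with TGFB1) and 5.21 ± 0.51 in KO, Eomes by 2.18 ± 0.32 and 2.87 ± 0.40, and the perforin gene Prf1 by 1.61 ± 0.26 and 2.74 ± 0.27. The adhesion molecule Selp (-3.73 in WT and -4.11 in KO) and the nitric oxide receptor chain Gucy1a1 (-2.14 and -3.71) fell in both as well.

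Of 20 genes of the TGFB/SMAD response 15 rose and 2 fell in WT and 14 rose and 2 fell in KO with TGFB1, the same numbers as when adjusted over the list alone, with the feedback regulators Pmepa1 (3.82 and 3.15) and Skil (1.74 and 1.52) in both (camera adjusted p = 1.23e-14 and 2.15e-14). This call held with an estimated correlation (adjusted p = 0.000195 and 0.000167). The list is not particular to TGFB1, as camera also called it upward for IL12 against no cytokine in both genotypes. On leaving out 1 library its highest camera adjusted p there was 0.0127 in WT and 0.00424 in KO. Those calls ended with an estimated correlation. Skil rose with IL12 by 0.57 in WT and 0.57 in KO. Of 14 genes of other T-cell lineages 10 rose and 1 fell in WT and 9 rose and 0 fell in KO, also when adjusted over the list alone, including the chemokine receptor Ccr6 (4.71 and 3.18); camera gave adjusted p = 1.39e-12 and 2.55e-14, and adjusted p = 0.000195 and 0.000147 with an estimated correlation. Of 28 genes of glycolysis and hypoxia 25 fell and 0 rose in WT, also when adjusted over the list alone, with the glucose transporter Slc2a1 at -0.83 and the phosphofructokinase Pfkp at -0.67. In KO 18 fell and 1 rose, and 21 and 1 when adjusted over the list alone. For this list the camera adjusted p was 1.7e-11 in WT and 7.84e-09 in KO, and adjusted p = 0.166 and 0.268 with an estimated correlation. Of 14 cytotoxic effectors 7 fell and 2 rose in WT, also when adjusted over the list alone, and 9 fell and 2 rose in KO, or 10 and 3 when adjusted over the list alone. Camera gave adjusted p = 0.00912 and 2.05e-09, and adjusted p = 0.27 and 0.011 with an estimated correlation. Of 32 effector and memory transcription factors 17 rose and 4 fell in WT, also when adjusted over the list alone, with Ikzf2 at 2.39. As a set the camera adjusted p was 4.87e-05, and adjusted p = 0.186 with an estimated correlation.

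Igha, the constant region of the IgA heavy chain (ENSMUSG00000095079, chromosome 12, 113254830 to 113260236), had 1363 counts in the 5 WT libraries with TGFB1 and 2 counts in those without cytokine, a ratio of 616 with a 95% interval of 170 to 5090. In KO it rose by 8.17 ± 0.66 on the log2 scale, from 0.0819 to 27.8 CPM. Pdpn, the membrane glycoprotein podoplanin, had ratios of 144 (95% interval 39.4 to 1190) in WT and 265 (95% interval 90.4 to 1290) in KO. In KO the thrombin gene F2, the growth cone gene Gap43 and the laminin gene Lamc3 had no counts without cytokine, and they were at least 123-fold, 84.9-fold and 71.5-fold higher with TGFB1. Among markers of B cells, Cd74 (2.35) and H2-Eb1 (1.72), of the MHC class II pathway, and Ighd (1.37) rose in WT with TGFB1, which are 3 of 10 measured members both over all genes and adjusted over the list alone. Tested as a list by camera, they had adjusted p = 0.0127, and adjusted p = 0.27 with an estimated correlation.

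TGFB1 changed 4439 genes in WT, 2255 up and 2184 down, and 2875 in KO, 1586 up and 1289 down. Changes of at least 2-fold were seen in 536 and 182 genes in WT and 442 and 288 in KO. Of the genes that rose in WT 944 also rose in KO, against 305.2 for independent lists, and of those that fell 628 also fell, against 240.2. The fold changes in WT and KO had a Pearson r of 0.705 across genes, which are not independent replicates.

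Whether the response to TGFB1 differed between the genotypes was tested as the difference of both responses. Rragd, a GTPase that carries amino acid signals to mTORC1 (ENSMUSG00000028278, chromosome 4, 32983037 to 33022180), responded more in KO by 2.08 ± 0.37 SE on the log2 scale (n = 5 per group, adjusted p = 0.0114). The same adjusted p belonged to Pros1, an anticoagulant protein that is also a ligand of TAM receptors (1.84 ± 0.32), the copper transporter gene Slc31a2 (1.29 ± 0.22) and Gpr183, a receptor that guides cells by oxysterols (-2.49 ± 0.44). Of the 26 genes of cholesterol synthesis 11 had a higher response in KO and 0 a lower one, such as Mvd (0.93 ± 0.19) and Nsdhl (0.78 ± 0.16), and 21 when adjusted over the list alone. The median was 0.71. The list test by camera gave adjusted p = 1.32e-15, and adjusted p = 0.391 with an estimated correlation. TGFB1 lowered 22 of these genes in WT and raised 1. For this list the camera adjusted p was 3.54e-07, and adjusted p = 0.303 with an estimated correlation. In KO it raised 5 and lowered 0 (camera adjusted p = 0.138).

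In the amino acid response list, 2 of 25 genes had a higher TGFB1 response in KO, Nupr1 (1.95 ± 0.47) and Aldh18a1 (0.74 ± 0.19), and 16 when adjusted over the list alone. By camera the list had adjusted p = 3.06e-10, and adjusted p = 0.391 with an estimated correlation. With the gene length trend removed, TGFB1 lowered 20 of these genes in WT and raised 2 (median -0.781, camera adjusted p = 1.19e-07). In KO it lowered 1 and raised 2 (median -0.089, camera adjusted p = 0.574). The higher response in KO is thus mainly a fall in WT that KO lacked. The list call in WT ended with an estimated correlation. Of 25 genes of the IL2/STAT5 response 4 had a higher response, among them Il2ra (1.25 ± 0.34, adjusted p = 0.0416), and 11 had a higher and 1 a lower one when adjusted over the list alone. As a set the camera adjusted p was 0.00031, and adjusted p = 0.571 with an estimated correlation. With the gene length trend removed, TGFB1 lowered 15 of this list in WT and raised 4 (median -0.722). In KO it lowered 5 and raised 4 (median -0.089). Il2ra itself fell with TGFB1 in WT (-1.02, adjusted p = 0.00179) and was not called in KO (0.23, adjusted p = 0.535). Of 14 genes in the list of cytotoxic effectors 2 had a lower and 1 a higher response in KO, and 4 and 1 when adjusted over the list alone. The 2 called lower were serpin genes, the granzyme inhibitor Serpinb9 (-1.53 ± 0.40) and Serpinb6b (-1.33 ± 0.31), and Lamp1 (0.31 ± 0.08) was called higher. The killing genes Gzma, Gzmb and Prf1 were not called in this fit (adjusted p = 0.343, 0.323 and 0.0716). Tested by camera, the list of cytotoxic effectors had adjusted p = 0.000916, and adjusted p = 0.391 with an estimated correlation. Id3, an inhibitor of E proteins, had a lower response in KO (-1.86 ± 0.35), the 1 call among 22 naive and memory genes, of which 5 were lower and 1 higher when adjusted over the list alone. The list test by camera gave adjusted p = 0.000293, and adjusted p = 0.571 with an estimated correlation. Pdcd1, which encodes the inhibitory receptor PD-1, differed by -1.13 ± 0.27 (adjusted p = 0.0262). The responses of Foxp3 (2.62 ± 1.02, adjusted p = 0.128), Itgae (-0.59 ± 0.75, adjusted p = 0.667) and Gzmb (-1.03 ± 0.63, adjusted p = 0.323) did not pass the test of the difference, with or without the animal number as a block. For Gzmb, WT library 62 with TGFB1 held 166.8 CPM, where the others of its group held 13.86 to 41.51 CPM. Without that library the fall of Gzmb in WT, given above, was close to that in KO. With the block the differences of Prf1, Il2 and Stat4, not called without it, passed (adjusted p = 0.016, 0.0188 and 0.0156).

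The numbers that follow are of genes called: TGFB1 response, KO minus WT. The comparison gave 387 genes, 189 with a higher and 198 with a lower response in KO. Leaving out 1 library lowered this number to 39 (WT with TGFB1, 75), 56 (WT with TGFB1, 67), 74 (KO without cytokine, 68), 79 (KO with TGFB1, 74), 89 (WT with TGFB1, 71), 95 (KO with TGFB1, 68), 115 (KO without cytokine, 74), 134 (KO without cytokine, 70), 144 (WT without cytokine, 72), 211 (WT without cytokine, 67), 215 (WT without cytokine, 62), 229 (KO without cytokine, 63) and 250 (WT without cytokine, 75). Without WT libraries 62 or 72 or KO library 73 with TGFB1 it was 2160, 620 and 875. With the animal number as a fixed block it was 1073. Without WT library 75 with TGFB1 the adjusted p was 0.0653 for Pdcd1, Nupr1 and Serpinb6b, 0.0932 for Serpinb9 and 0.0835 for Lamp1, and without KO library 74 with TGFB1 it was 0.0987 for Il2ra and 0.0894 for Aldh18a1.

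IL12 against no cytokine asks the same of the effector-driving cytokine. Ifng, the effector cytokine interferon gamma (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892), rose from 9.52 to 796.1 ± 520 CPM (SD, n = 5) in WT and from 14.99 to 637.6 ± 448 CPM (SD, n = 5) in KO, which are log2 fold changes of 6.37 ± 0.53 SE (adjusted p = 5.45e-09) and 5.43 ± 0.51 SE (adjusted p = 3.4e-08). Tbx21, the factor T-bet that directs type 1 responses (ENSMUSG00000001444, chromosome 11, 97098071 to 97115331), rose by 1.83 ± 0.19 and 1.62 ± 0.19, Gzmb by 2.11 ± 0.42 and 2.38 ± 0.43, and the IL12 receptor chain Il12rb2 by 1.29 ± 0.26 and 1.75 ± 0.26. Eomes rose by 1.16 ± 0.27 and 1.61 ± 0.29, although the call of Eomes in WT ended without WT libraries 72 and 75 with IL12 (adjusted p = 0.0537). The ATP-gated channel gene P2rx3 rose by 7.78 ± 0.76 and 6.85 ± 0.81, and the proton pump gene Atp6v0d2 by 7.48 ± 0.80 and 4.90 ± 0.62. Il23r, a receptor chain of IL23, had no counts without cytokine and was at least 124-fold higher in WT and 102-fold higher in KO. Il10 had a ratio of 93.3 (95% interval 31.6 to 455) in WT. Among the largest falls in both genotypes were Iigp1 (-2.06 and -1.97), an interferon-induced GTPase, the costimulatory ligand gene Cd86 (-1.93 and -1.95) and Tspan2 (-2.08 and -1.73).

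Of 25 genes of the IL12/STAT4 response 18 rose and 1 fell in WT and 17 rose and 1 fell in KO, with 20 and 18 rising and 1 falling in each when adjusted over the list alone, including Prdm1 (3.33 and 3.44), which drives terminal effector cells, and the IL18 receptor chain Il18r1 (3.00 and 2.73); camera gave adjusted p = 6.66e-20 and 2.27e-20. This call held with an estimated correlation (adjusted p = 0.0479 and 0.0278). Of 14 cytotoxic effectors 11 rose and 1 fell in WT and 8 rose and 0 fell in KO, also when adjusted over the list alone, with the death ligand Tnfsf10 (2.13 and 2.06) and the granule gene Nkg7 (0.95 and 0.74) in both. The camera adjusted p was 6.35e-08 in WT and 5.9e-06 in KO, and adjusted p = 0.0479 and 0.0827 with an estimated correlation. Of 32 interferon-gamma response genes 18 fell and 1 rose in WT, also when adjusted over the list alone, and 16 fell and 1 rose in KO, or 19 and 2 when adjusted over the list alone, with Irgm1 (-1.02 and -0.97) and Tgtp2 (-1.37 and -1.44), GTPases of cell-autonomous immunity, in both. For this list the camera adjusted p was 2.37e-13 and 2e-15, and adjusted p = 0.156 and 0.132 with an estimated correlation. Of 24 cytokine receptors 11 rose and 3 fell in WT and 10 rose and 2 fell in KO, or 12 and 3 and 11 and 3 when adjusted over the list alone, with the IL33 receptor Il1rl1 (4.29 and 4.19) and Tgfbr3 (2.47 and 2.88) in both. By camera the list had adjusted p = 0.000256 and 9.69e-07, and adjusted p = 0.104 and 0.0278 with an estimated correlation. Of 30 genes of the G2 and M phases 9 fell in WT and 8 in KO, or 14 and 10 when adjusted over the list alone, by small amounts, as in Aurkb (-0.24 and -0.26) (camera adjusted p = 4.45e-05 and 7.49e-06, adjusted p = 0.305 and 0.259 with an estimated correlation), and the call of Aurkb in WT ended without WT libraries 72 and 75 with IL12 (adjusted p = 0.101). Of 13 FURIN substrates and TGFB activators 7 rose and 1 fell in KO, and 7 and 2 when adjusted over the list alone. Their camera adjusted p was 0.0364, and adjusted p = 0.254 with an estimated correlation, and the call ended without KO library 68 in either condition or KO 70 with IL12 (adjusted p of up to 0.0651).

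The next numbers are of genes called: IL12 vs no cytokine in WT, with 2209 genes, 1236 up and 973 down, and genes called: IL12 vs no cytokine in KO, with 1668, 995 up and 673 down. Of the genes that rose in WT 714 also rose in KO, where 105 are expected of independent lists, 388 of those that fell also fell, where 55.9 are expected, and 0 went opposite ways. The number in WT was 1328 without WT library 72 with IL12, 1459 without WT 75 and 764 without both, and in KO it was 1044 without KO library 74 with IL12. The response to IL12 differed between the genotypes in 0 genes by edgeR, with 513 genes at an unadjusted p below 0.05, and DESeq2 and limma-voom with and without the block also gave 0. The differences were -0.94 ± 0.66 for Ifng, -0.72 ± 0.42 for Furin and -0.21 ± 0.26 for Tbx21. Of 32 lists, oxidative phosphorylation was lower in the IL12 response of KO (median -0.15, 0 members called over all genes or adjusted over the list alone, camera adjusted p = 1.39e-10, adjusted p = 0.781 with an estimated correlation, 0.753 by fry and 0.105 without WT libraries 72 and 75 with IL12), as were cytokines and chemokines (0 called, camera adjusted p = 0.0203, adjusted p = 0.958 with an estimated correlation). The call of the cytokine list ended without any 1 of 8 libraries. These were WT 71, WT 72, KO 68 and KO 70 without cytokine and WT 62, WT 72, KO 63 and KO 73 with IL12, and the highest adjusted p was 0.135, without KO 70.

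The remaining lists of T-cell programmes follow. Of 6 measured proprotein convertases 0 were called for KO against WT without cytokine (camera adjusted p = 0.805). With TGFB1 2 rose and 1 fell, and 2 and 2 when adjusted over the list alone. That list's median was -0.03, its mean 0.27 and its test upward (camera adjusted p = 0.629). Of 18 genes of tissue residency 7 rose and 3 fell with TGFB1 in WT, also when adjusted over the list alone (camera adjusted p = 0.0636, and 0.0384 with the animal number as a block). In KO 4 rose and 4 fell (camera adjusted p = 0.138), and for KO against WT with TGFB1, 2 rose and 4 fell (camera adjusted p = 0.861), the same numbers as when adjusted over the list alone. Of 22 genes of the unfolded protein response 7 rose and 1 fell with IL12 in WT, and 12 and 2 when adjusted over the list alone. Their camera adjusted p was 0.00393, and adjusted p = 0.29 with an estimated correlation. Of 22 p53 targets 7 rose and 1 fell there, and 12 and 2 when adjusted over the list alone. By camera the list had adjusted p = 0.0126 for them, and adjusted p = 0.305 with an estimated correlation. Without WT libraries 72 and 75 with IL12 that call ended. Of 8 NK-type receptors 4 rose and 0 fell with IL12 in WT, also when adjusted over the list alone. That gave a camera adjusted p = 0.0061, and adjusted p = 0.163 with an estimated correlation. Of 30 genes of the S phase 9 fell and 1 rose with IL12 in WT, also when adjusted over the list alone. The replication genes had a camera adjusted p = 0.00136, and adjusted p = 0.272 with an estimated correlation.

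Markers of other cells and of handling were measured beside these groups. Of 6 dendritic-cell markers 4 rose with IL12 in WT, including Fscn1 (3.92), which bundles actin, and the factor Batf3 (2.63), also when adjusted over the list alone. By camera the list had adjusted p = 0.0106 for these markers, and adjusted p = 0.163 with an estimated correlation. Of 6 CD4 T-cell markers 3 rose and 1 fell with TGFB1 in WT (camera adjusted p = 0.211). Of 6 macrophage, monocyte and granulocyte markers 2 rose (camera adjusted p = 0.267), and of 4 markers of NK and gamma-delta T cells 1 rose and 2 fell (camera adjusted p = 0.379). These numbers were the same when adjusted over the list alone. Of 18 immediate early genes 5 rose and 1 fell with IL12 in WT, also when adjusted over the list alone. They had a camera adjusted p = 0.0335, and adjusted p = 0.259 with an estimated correlation. That call ended without WT library 71 or 72 of those without cytokine (adjusted p of up to 0.0748), and with the gene length trend removed (adjusted p = 0.13).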

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

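The tests on Igha and on exchanged labels were chosen after seeing the results, and the other tests were set before their outcome was known. Of 186 groups of 5 values 21 held 1 library far from the other 4. For independent, normally distributed values about 1 in 20 groups, or 9.3, would be set apart. CPM of many genes in the same libraries need not meet this, so 21 against 9.3 does not show an excess. KO library 74 with IL12 held 5 of them: Furin at 463.5 CPM, Ifng at 1425, Prf1 at 389.7, Tbx21 at 177.3 and Il2ra at 1774. WT library 62 with TGFB1 held 4, with Ifng at 23.74 CPM, Gzmb at 166.8, Tnf at 15.23 and Il2ra at 867.4. WT library 71 without cytokine held 4, with Tcf7 at 507.7 CPM, Itgae at 7.302, Tgfb1 at 217 and Cxcr3 at 5.889. The others were Il2 at 5.116 CPM (WT 62 without cytokine), Gzma at 4.228 (WT 75 with TGFB1), Prf1 at 26.32 (KO 68 with TGFB1) and 316.4 (WT 75 with IL12), Tgfbr1 at 12.84 (WT 72 with IL12), Cd69 at 131.6 (KO 73 with IL12) and Cxcr3 at 7.514 (WT 71 with IL12). The total of WT library 62 with IL12 was 7306151 counts (7.31 M).

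The response to TGFB1 differed between KO and WT, by the test of the difference, in 387 genes. Among key genes these were Il2ra (1.249) and Pdcd1 (-1.127). The genes with the smallest p were Slc31a2 (1.293), Pros1 (1.843), Rragd (2.076), Gpr183 (-2.489), N4bp1 (0.709), Smim8 (-0.904), Exoc3 (0.46) and Fndc3a (0.685).

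Genes of oxidative phosphorylation had a median log2 fold change of -0.141 in KO against WT with IL12. With the gene length trend removed it was -0.072, with camera adjusted p = 0.000103, between the predictions for and against a length bias, so that test could not tell. Without WT libraries 72 and 75 it was -0.035, with 0 members called and camera adjusted p = 0.147. The lower level may therefore come from these 2 libraries rather than from the genotype.

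Igha was at 5.21 to 55.8 CPM in the 10 libraries with TGFB1 and at most at 0.547 CPM in the others. RNA from B cells or plasma cells would bring light chains at a similar level, but these held 0.459% of the Igha level. This value argues against RNA from such cells as the source, although the prediction for the test was written once the values were known. The design gives TGFB1 itself as the biological explanation, which could act on the heavy-chain locus in T cells, and 0.459% leaves that open.

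With WT animal 62 grouped with KO and KO animal 73 with WT, more genes were called than with the labels as given, 2022 against 1099 without cytokine. The same exchange called 83 genes against 35 with IL12 and 3568 against 2400 summed per animal. For the difference in the TGFB1 response the exchange called 2107 against 320, and for that in the IL12 response 0 against 0. With the labels as given 19 genes separated the genotypes without overlap in all 3 conditions, with 51 for this exchange and at most 1 for the other 24 exchanges. The prediction for this test was written once the values were known, so it does not settle whether both animals were mislabelled. Among females, with animal 73 among WT and with the labels as given, 2611 and 1077 genes were called without cytokine, 246 and 69 with IL12, and 5015 and 4710 with TGFB1. Sex as the whole cause did not meet its prediction without cytokine, the 1 condition it was set for, and the cause of the pattern is left open.

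For each comparison 100 splits of its libraries were fitted, and the number of splits calling at least as many genes as the real split, itself included, was counted. For KO against WT it was 2 without cytokine (1099 real, 2022 in the highest other), 2 with TGFB1 (2271 and 4949), 3 with IL12 (35 and 934) and 2 summed per animal (2400 and 3568). For TGFB1 it was 2 in WT (3751 and 4444) and 1 in KO (3474 and 142), and for IL12 it was 1 in WT (1642 and 182) and 1 in KO (2407 and 0). For the difference in the TGFB1 response it was 2 (320 and 2107), and for that in the IL12 response 100 (0 and 141). Another split called more genes than the real one in every comparison of KO with WT. This also held for TGFB1 in WT and for the difference in the TGFB1 response. In KO against WT the second-highest other split called 993 genes without cytokine and 2105 with TGFB1. The splits of KO against WT also ignore the order of the animal numbers. Chance is left open in these comparisons and in the last. For TGFB1 in KO and IL12 in each genotype no other split called as many genes as the real one. The split calling 934 genes with IL12 put animals 62, 67, 63, 68 and 70 against the higher numbers, which points to a structure of the samples along the animal number. Among the 16 splits of the cytokine comparisons that part as many pairs as the real one, the highest other called 0 genes. The real split is at best 1 of 16 there, too large a share to exclude chance.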

How the results depend on the processing

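The tests without WT libraries 72 and 75 with IL12, with a term for animal numbers above 70, with the gene length trend removed and with thinned libraries were chosen after seeing the data. No result reversed. Of 461 calls of named genes, DESeq2 kept 459, females only 452 and RLE size factors 461. The fits on the compared groups lost 48, and thinning lost 12. Pooled over all fits that left out 1 library, and counted once per call and fit, 501 were lost and 4369 kept. Without WT libraries 72 and 75, 57 of 119 were lost. Of key-gene results not called, 11 became calls with the fixed replicate block and 89 did not. Of the list calls, 89 were lost and 9 kept with an estimated correlation. With the term for animal numbers above 70, 3 calls of named genes were lost and 28 kept, 2 key genes were newly called, among them Furin (lower in KO with IL12), and 2 list calls were lost and 2 gained.

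Numbers of genes follow by comparison, with the range over single libraries left out. For genes called: KO vs WT, no added cytokine, with 246, the range was 7 to 568, with 68 at an absolute log2 fold change of at least 1, 460 by DESeq2 and 1099 on the compared groups. For genes called: KO vs WT, with TGFB1, with 4166, it was 2814 to 5367, with 521 and 2271 for the first and last of these settings. For genes called: KO vs WT, with IL12, with 794, it was 164 to 1532, with 104 and 35, 504 with no filter and 8 without WT 72 and 75. For genes called: KO vs WT, 3 libraries summed per animal number, with 2400, it was 148 to 3741, with 209 at that fold change. For genes called: TGFB1 vs no cytokine in WT, it was 3506 to 5353, with 718, and for genes called: TGFB1 vs no cytokine in KO, 2294 to 2889, with 730. For genes called: IL12 vs no cytokine in WT, it was 1328 to 2697, with 509, and 764 without WT 72 and 75, and for genes called: IL12 vs no cytokine in KO, 1044 to 1588, with 419. For genes called: TGFB1 response, KO minus WT, with 387, it was 39 to 2160, with 132 at that fold change, 774 by DESeq2 and 1257 in females. With the replicate block it was 1073 as fixed, 955 as random by limma-voom and 1290 with the length trend also removed. For genes called: IL12 response, KO minus WT, it was 0 to 0. The block moved no other count by more than 1.5 times. A fold change minimum lowers counts by construction, and for the other settings the cause was not tested.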

Other observations

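The tests given here were chosen after seeing the results. With the labels as given, 19 genes separated KO from WT without overlap in all 3 conditions, 16 lower and 3 higher in KO. Among the lower ones were Tspan9, the nucleic acid sensor Zbp1, the GTPase Gbp4 and the immunoproteasome genes Psmb8, Psmb9 and Psmb10, which make peptides for MHC class I. The gene Tspan9 (ENSMUSG00000030352, chromosome 6, 127961396 to 128143594) averaged 1.569 CPM in WT and 0.3009 CPM in KO without cytokine. On chromosome 7, which holds Furin, lay 3 of the 19, spread along it. Selenow starts at 15917208, Dgat2 at 99153658 and Taldo1 at 141392199. This number was not compared with the share of all tested genes on that chromosome.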
